A study of Mus musculus with 9 samples.

How the data were processed

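RNA was measured in primary immature neurons cultured from mouse embryos of embryonic day 14. Per the labels' protocols, the neurons were kept for 2 days in vitro in a medium with fetal bovine and horse serum, and were then left untreated or given 2-deoxyglucose (2-DG) at 1 mM or 10 mM for 6 h. The series design names independent replicates, 3 per group, without saying which cultures they were. Per the labels' protocols, cDNA was made with a whole-transcriptome amplification kit, followed by a stranded library kit with removal of ribosomal RNA, and paired-end reads were aligned to the mouse genome mm10 with STAR. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq. The gene annotation and the strand setting of the counting are not given in the sources used here, so the value of a gene that overlaps another gene on either strand is uncertain to that extent.

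The deposited table holds raw read counts per gene, as whole numbers, with 1 column per library and 24061 rows. Its 9 columns were assigned to groups by the library titles in the labels. The unit was checked on the values: they were whole numbers that summed to between 40.1 M and 48.2 M per library. Of the table's rows, 1 names no gene (its label reads enhancer, 3 kb and as). Its position and meaning are not given in the sources used here, and it was kept out of the library sizes and the tests of the report. A separate fit with the entry added to the genes tested was made after its counts were seen and stands in the closing section. Another 4 rows share a pair of symbols that spreadsheet software alters and were not named.

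Genes were filtered with filterByExpr of edgeR (a minimum count of 10 and a minimum total count of 15), which left 15153 genes. Library sizes were scaled by trimmed means of M values (TMM). A quasi-likelihood negative binomial model was fitted to all 9 libraries with 3 groups and no block, and each comparison was tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a single gene in the text comes from this test unless another is named. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are given as CPM (counts scaled to a common library size) with TMM factors, as mean ± SD of the libraries of a group. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Standard errors cover counting error and the spread between libraries, and reads without molecular identifiers are not independent molecules. The bootstrap intervals of the closing section resample genes from a single fit. They therefore do not cover the spread between libraries, and they treat genes as independent.

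Gene lists for pathways, complexes and cell types, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists were targets of ATF4 and CHOP (the integrated stress response), ER chaperones and ER-associated degradation (targets of ATF6 and XBP1), cytosolic aminoacyl-tRNA synthetases, glycolysis and glucose or lactate transport, glucose-sensing targets of MondoA and ChREBP, targets of hypoxia-inducible factors, and hexosamine, sugar nucleotide and N-glycan precursor synthesis. Further lists were neurotrophins and their receptors, immediate early genes, cholesterol synthesis, ketone body and fatty acid oxidation, the AMPK, fasting and FOXO response, autophagy and lysosome, the antioxidant response (NRF2 targets), and the cytosolic heat shock response. Mitochondrial protein quality control, p53 targets, the cell cycle, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, and synapse and neuronal excitability were listed as well. Cell type lists covered immature neurons, GABAergic interneurons, radial glia and neural progenitors, astrocytes, the oligodendrocyte lineage, microglia and macrophages, endothelial cells and pericytes, fibroblasts and meninges, and erythroid cells. A list of the mitochondrially encoded respiratory chain was not analysed here. Each of the 30 lists was tested against all other genes with camera (limma) at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone. The list of ATF4 and CHOP targets includes the genes of these factors, Atf4 and Ddit3. Some genes stood in more than 1 list, such as Slc7a11 (ATF4 targets and NRF2 targets), Ldha and Pfkfb3 (glycolysis and hypoxia), Gdf15 (ATF4 targets and p53 targets) and Aldoc (glycolysis and astrocytes).

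By the rule for named genes, Bdnf, Atf4, Ddit3, Hspa5 and Txnip were named in every comparison. Added to them were the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with an average log2 CPM of at least 1, a symbol that is not a predicted gene or clone name, and all libraries of 1 group above all of the other (3 and 3 genes for 10 mM against 1 mM). From each of the 8 lists with the smallest camera p in a comparison with the control, the 3 members with the smallest p were added, and from every other list at most 2. A gene named for 1 comparison could be given for the others. Single values of some list members are not reported here. Members that went against their list, and other genes outside the rule, were chosen after their values were seen. Positions are those of GENCODE release M21 on GRCm38, which matched 14429 of the genes tested by symbol. Ddit3 was not matched to a position, because a pair of entries share its symbol. The Ddit3 entry that overlaps Mars lies on chromosome 10 (127290774 to 127296288, plus strand).

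Alternatives were RLE size factors, library totals alone, no filter on low counts, a filter of at least 50 counts in 3 libraries, DESeq2, limma-voom, a fit to only the 6 libraries compared, the replicate number as a block, counts thinned to the shallowest library, leaving out ribosomal RNA and the 20 genes with the largest shares, a minimum fold of 1.5 (glmTreat), and leaving out each library in turn. For lists they were an estimated correlation, fry and the replicate block. Unlike camera, fry asks whether the members of a list change at all, not whether they change more than other genes. A replicate block combined with an estimated correlation was added after the data were seen. Replicate numbers were checked for pairing on residuals from the group means: the 9 pairs of libraries with the same number had correlations across genes of 0.351 to 0.518, and the 18 pairs with different numbers had correlations of -0.344 to -0.112. Libraries with the same number were therefore paired in the data, and the main test, fixed beforehand without a block, leaves this pairing out. With the block, 1520 of 1520 main calls were kept at 1 mM, 7535 of 7538 at 10 mM and 4731 of 4731 between the doses. Further genes passed only with the block, so a gene that did not pass the main test may pass there. For the correlation between the doses, 100 simulations of unchanged groups sharing controls gave the comparison, since 3 controls cannot be split into equal groups.

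The fit was tested on simulated data with known changes. For 1 mM against control, 14975 genes were tested, and 74.6% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 4 unchanged genes called. For 10 mM against control, 14976 genes were tested, and the recovered shares were 76.1%, 91% and 100% at the same folds, with 10 unchanged genes called. The simulated changes were in 67, 67 and 66 genes above a floor of expression, balanced up and down, in libraries without pairing. The shares therefore need not hold for low-count genes, or for the real 10 mM comparison, where 49.7% of genes passed.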

Results

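Gene expression was measured by RNA sequencing in primary immature mouse neurons kept for 6 h without treatment or with 2-deoxyglucose (2-DG), a glucose analogue that is phosphorylated by hexokinase and blocks the use of glucose. There were 3 libraries from untreated cultures, 3 from cultures with 1 mM 2-DG and 3 from cultures with 10 mM. Gene counts summed to 40.1, 42.4 and 45 M in the control libraries (M, mega), to 47.7, 40.6 and 43.8 M at 1 mM and to 45.4, 43.3 and 48.2 M at 10 mM, for replicates 1, 2 and 3 in turn. In a principal component analysis, the component with the largest share held 51.7% of the variance and the next held 14.4%. The series title names transcription of Bdnf and a pathway from endoplasmic reticulum (ER) stress to the transcription factor ATF4, and the comparisons below ask how these genes and 30 fixed gene lists differed between doses. The share of counts on the ribosomal RNA gene Rn45s was 1.01 ± 0.0458% in the control, 0.691 ± 0.167% at 1 mM and 0.544 ± 0.0167% at 10 mM (SD, n = 3).

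The comparison of 1 mM with control asks what the low dose changed within 6 h. Neurons given 1 mM had more RNA of the ER stress and amino acid response: Hspa5, the main chaperone of the ER, rose 4.20-fold, Ddit3, the stress transcription factor CHOP, rose 7.58-fold, and Trib3, a pseudokinase induced by ATF4 and CHOP, rose 54.1-fold. Bdnf, a secreted growth factor for neurons, rose 1.51-fold. Of 18 marker genes of microglia, the brain's resident macrophages, 11 fell, led by the chemokine receptor Cx3cr1, whose mean level went from 8.01 to 0.265 CPM. The list of these markers lost its call with an estimated correlation (adjusted p = 0.176).

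Bdnf (chromosome 2, 109674700 to 109727007, plus strand) stood at 3.70 ± 0.706 CPM in the control and 5.60 ± 0.506 CPM at 1 mM (SD, n = 3), with 132 to 207 and 217 to 275 counts per library. Its log2 fold change was 0.59 (SE 0.15, adjusted p = 0.0281 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 7.26e-05 with the replicate block). This call was lost without control replicate 1 (0.51, adjusted p = 0.104), control replicate 2 (0.53, 0.0728), 1 mM replicate 1 (0.62, 0.068) or 1 mM replicate 3 (0.52, 0.104), in a fit to the 6 libraries compared (0.59, 0.0557) and with a minimum fold of 1.5. The antisense gene Gm45346 overlaps Bdnf on the other strand. Atf4 (chromosome 15, 80255184 to 80257541, plus strand), the central transcription factor of the integrated stress response, rose from 275 ± 47.4 to 654 ± 132 CPM (log2 fold change 1.25, SE 0.15, adjusted p = 4.81e-04). Ddit3 rose from 13.2 ± 0.557 to 100 ± 17.9 CPM (2.92, SE 0.12, adjusted p = 9.35e-08). Hspa5 (chromosome 2, 34771970 to 34777547, plus strand) rose from 346 ± 8.51 to 1456 ± 142 CPM (2.07, SE 0.074, adjusted p = 7.94e-08). Txnip (chromosome 3, 96557957 to 96561883, plus strand), an inhibitor of glucose uptake, rose from 11.9 ± 10.5 to 144 ± 15.4 CPM (3.59, SE 0.43, adjusted p = 4.33e-04). Control replicate 2 held 24.1 CPM of Txnip against 5.42 and 6.39 in the other control libraries, and without it the log2 fold change was 4.61 (adjusted p = 4.54e-08). The tested antisense gene Gm15441 overlaps Txnip on the other strand.

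**Figure D1:**
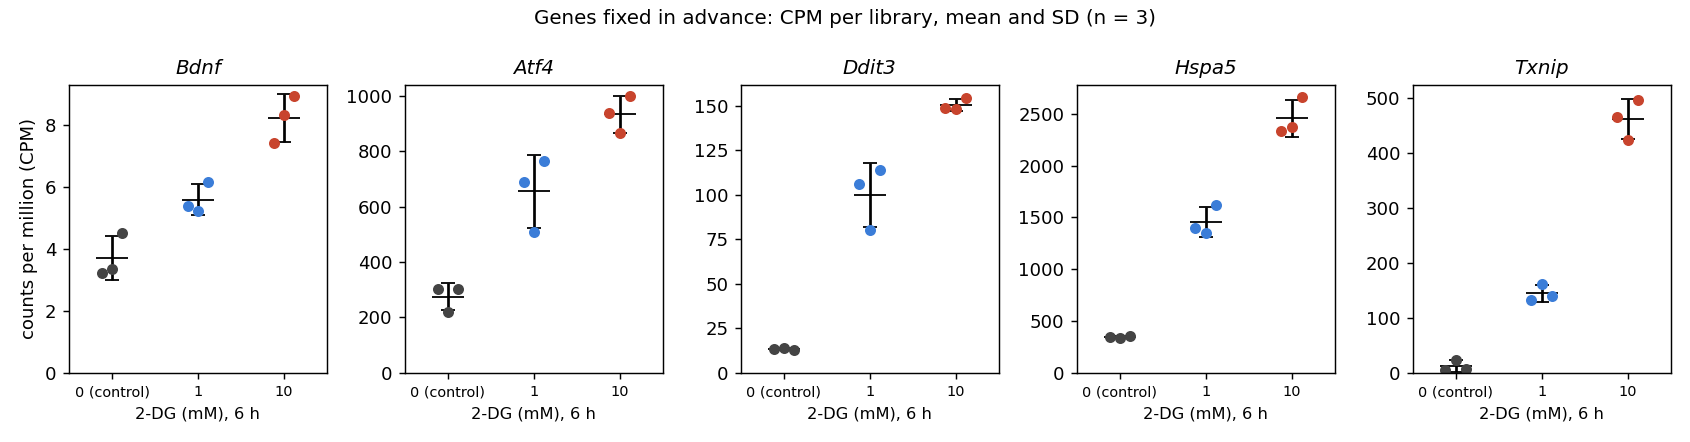
Levels in CPM (vertical axes, linear) of the 5 genes named in every comparison, with 1 point per library of the control, 1 mM and 10 mM groups and lines for mean and SD (n = 3). All 5 means rose with dose, Bdnf from 3.70 to 8.23 CPM and Hspa5 from 346 to 2459 CPM.

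All 40 tested genes of the list of ATF4 and CHOP targets, which includes Atf4 and Ddit3 themselves, rose at 1 mM. They did so over all genes tested and adjusted over the list alone. The median log2 fold change was 2.02, with a camera adjusted p too small for the software to represent. Among the listed genes were Trib3 (5.76, SE 0.18), Asns, which makes asparagine (2.31, SE 0.086), and Slc7a5, a transporter of large neutral amino acids (2.38, SE 0.086). The stress-induced nuclear protein gene Nupr1 (4.49, SE 0.24) and Slc7a11, which imports cystine (3.92, SE 0.18), had some of the largest rises of all genes, as did Trim66 (4.33), Cass4 (4.19) and Cyb5r2, whose rise of 4.38 was 3.77 without 1 mM replicate 3. Of 40 genes of ER chaperones and ER-associated degradation, 37 rose and 0 fell (39 and 0 adjusted over the list alone; median 0.95, camera adjusted p = 3.53e-169). Examples were the ER stress gene Creld2 (2.00, SE 0.061) and the ER chaperone Hyou1 (1.69, SE 0.057). Dnajc10, Edem2 and Crebrf, chosen after their values were seen, did not pass the main test (0.17, 0.20 and -0.075). With the replicate block, 39 of the 40 ER genes rose and 0 fell. Of 20 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 14 rose and 0 fell (the same adjusted over the list alone; median 0.80, camera adjusted p = 1.98e-49). Among them were Nars (1.27), Iars (1.19) and Mars (1.15), which overlaps the end of Ddit3 on the opposite strand. With an estimated correlation these lists kept adjusted p = 0.00144, 0.00363 and 0.0435. With the replicate block alone, camera gave adjusted p = 2.24e-48, 1.26e-38 and 1.07e-14, and fry without the block gave 3.14e-05, 3.14e-05 and 5.15e-04. With the block and an estimated correlation together each had adjusted p = 0.204, in a test that 0 of the 30 lists passed. Microglial markers moved in the same libraries, with a median of -0.86.

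Of 42 genes that make sugar nucleotides and the precursors of N-glycans, 16 rose, 1 fell and 25 did not pass at 1 mM (18 and 1 adjusted over the list alone; 21 and 2 with the replicate block). The median was 0.13 and the camera adjusted p = 1.35e-07, which was 1.13e-06 with the replicate block, 0.0486 with an estimated correlation and 0.21 with both. Rpn1, a subunit of the oligosaccharyltransferase, rose by 0.74 (SE 0.051), Ogt, which attaches N-acetylglucosamine to proteins, by 0.54 (SE 0.039), and Gfpt1, the entry enzyme of the hexosamine pathway, by 0.40 (SE 0.039). The member that fell was Mgea5, which removes N-acetylglucosamine from proteins (-0.68, SE 0.072). Of 7 glucose-sensing targets of MondoA and ChREBP, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.53, camera adjusted p = 2.42e-07, 0.0435 with an estimated correlation, 0.0128 with the replicate block, 0.303 with both). They included Txnip and its relative Arrdc4 (2.41, SE 0.11); the rise of Klf10 (0.53, adjusted p = 0.0319) was lost without control replicate 1 (0.43, 0.117), control replicate 3 (0.49, 0.111), 1 mM replicate 2 (0.46, 0.0827), 1 mM replicate 3 (0.52, 0.0885) or 10 mM replicate 1 (0.53, 0.0527).

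Of 18 microglial and macrophage markers, 0 rose and 11 fell at 1 mM (12 adjusted over the list alone; median -0.86, camera adjusted p = 1.04e-12). With an estimated correlation the call was lost (adjusted p = 0.176). Cx3cr1, a receptor on microglia, had a log2 fold change of -4.89 (SE 0.27, adjusted p = 8.74e-07), C1qa and C1qb, parts of the first complement component, had -1.78 (SE 0.27) and -1.82 (SE 0.30), and Cd68, a lysosomal protein of macrophages, had -0.82 (SE 0.12). The annotated span of Cx3cr1 is overlapped on its own strand by Gorasp1 and Csrnp1. Further genes with some of the largest falls stand in none of the fixed lists: Plau, the urokinase (-3.06), Tlr13, an innate immune receptor (-2.85), Msr1, a scavenger receptor (-2.71), and Fcgr3, an antibody receptor (-2.13).

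**Figure D2:**
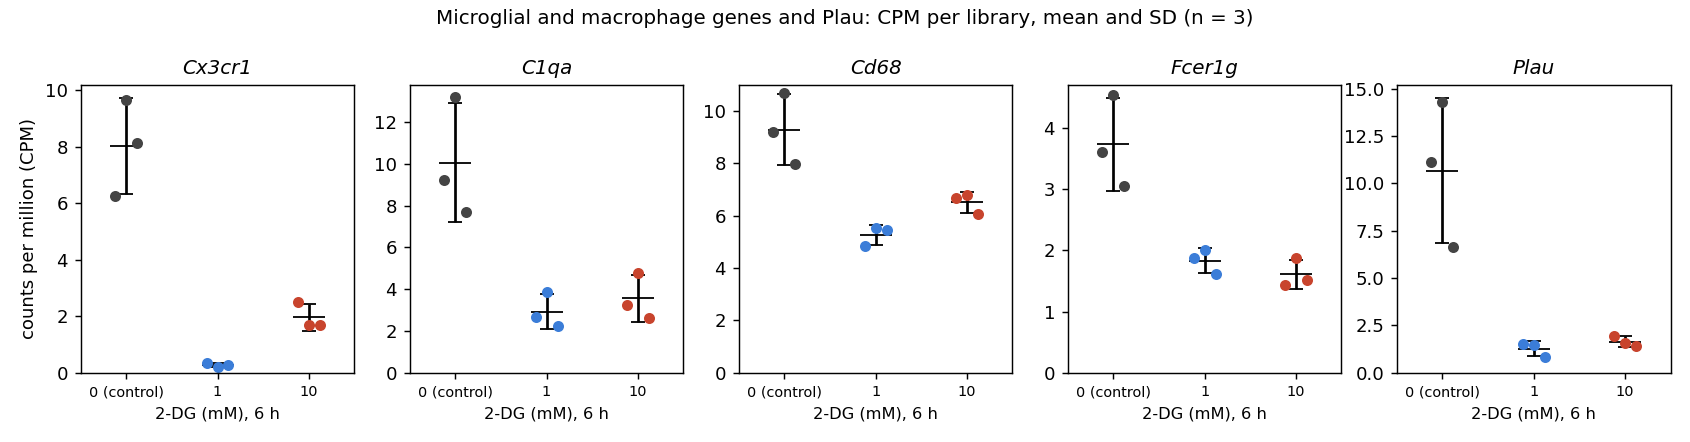
Levels in CPM (vertical axes, linear) of Cx3cr1, C1qa, Cd68, Fcer1g and Plau, with 1 point per library of the 3 groups and lines for mean and SD (n = 3). Cx3cr1 had mean levels of 8.01, 0.265 and 1.96 CPM in the control, 1 mM and 10 mM groups.

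Of 46 cell cycle genes, 0 rose, 6 fell and 40 did not pass at 1 mM (11 adjusted over the list alone; 1 rose and 34 fell with the replicate block; median -0.26, camera adjusted p = 1.85e-06, adjusted p = 0.716 with an estimated correlation). Ccne2 (-1.24, SE 0.17) and Ccne1 (-1.19, SE 0.17), the E-type cyclins of the entry into S phase, and E2f2, a transcription factor of the same step (-0.98, SE 0.19), were among them. Of 58 nuclear genes of the respiratory chain, 0 rose and 6 fell (7 adjusted over the list alone; 25 with the replicate block; median -0.081, camera adjusted p = 0.00123, adjusted p = 0.664 with an estimated correlation, and 0.0567 without control replicate 1). Among them were Cox6b1 (-0.31, SE 0.039) and Uqcrh (-0.39, SE 0.054). Of 26 cholesterol synthesis genes, 0 rose and 5 fell (6 adjusted over the list alone; 2 rose and 15 fell with the replicate block; median -0.15, camera adjusted p = 0.00279, adjusted p = 0.484 with an estimated correlation). Acat2, which joins acetyl-CoA units, fell (-0.31, SE 0.047). Of 20 radial glia and progenitor markers, 0 rose and 3 fell (the same adjusted over the list alone; 1 and 12 with the replicate block; median -0.16, camera adjusted p = 0.0338). That list test was lost with an estimated correlation (adjusted p = 0.742) and without control replicate 1 (0.0829), control replicate 3 (0.229) or 1 mM replicate 2 (0.326).

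The other 20 lists did not pass camera at 1 mM (adjusted p from 0.0602 to 0.915); their counts adjusted over the list alone were the same unless given, and those with the replicate block (blocked) follow where they differ by over 1.5 times. Of 26 NRF2 targets, 3 rose and 10 fell (3 and 11 adjusted over the list alone; 5 and 15 blocked), with a median of -0.13 and a mean of 0.10. Slc7a11 and Hmox1, which degrades haem (0.82), rose, and Prdx1, a peroxidase, fell (-0.41, SE 0.051); this list passed with the block (0.00305) but not with the block and an estimated correlation (adjusted p = 0.204). Of 26 glycolysis and transport genes, 1 rose, Pfkfb3 (0.27, SE 0.051), and 2 fell, Tpi1 (-0.42, SE 0.056) and Ldha (-0.40, SE 0.072), against 3 and 11 blocked. Of 21 hypoxia targets, 4 rose and 2 fell (5 and 5 blocked). An example was Vegfa, a growth factor of blood vessels, at 2.03 (SE 0.092). Of 16 neurotrophins and receptors, 1 rose, Bdnf, and 3 fell (2 and 5 blocked). Among them were the growth factor Igf1 (-0.78, SE 0.13) and Sort1, a sorting receptor for neurotrophins (-0.28, SE 0.050). Of 36 immediate early genes, 3 rose, with Jun at 0.44 and Nfil3 at 0.48, and 3 fell (10 and 7 blocked). Of 42 autophagy and lysosome genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone; 11 and 14 blocked). Examples were Atg12 at 0.28 and Rragd at -0.35. Of 19 genes of mitochondrial protein quality control, 2 rose and 0 fell (7 and 6 blocked), with the chaperone Hspa9 at 0.83 (SE 0.095). Of 25 p53 targets, 2 rose and 2 fell (6 and 10 blocked). Examples were Gdf15 at 3.41 (SE 0.27) and Dcxr at -0.66. Of 78 ribosomal protein genes, 2 rose and 0 fell (23 and 1 blocked, where the list passed with 0.0128 but had adjusted p = 0.608 with an estimated correlation too). An example was Rpl10 at 0.58.

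Among the remaining lists at 1 mM, 28 ketone body and fatty acid oxidation genes had 0 rises and 1 fall (0 adjusted over the list alone; 2 and 12 blocked, list adjusted p = 0.00729, and 0.204 with an estimated correlation too), and 24 heat shock genes had 0 and 0 (0 and 9 blocked, list adjusted p = 0.0349, and 0.251 with an estimated correlation too). None of 44 synapse genes (7 and 2 blocked) and none of 21 AMPK and FOXO genes (3 and 6 blocked) passed edgeR's test. Of 25 markers of immature neurons, 0 rose and 1 fell, Cd24a, a surface protein of young neurons (-0.31, SE 0.063; 1 and 6 blocked). Of 17 GABAergic markers, 1 rose and 0 fell (0 adjusted over the list alone; 2 and 1 blocked). Of 11 oligodendrocyte markers, 0 rose and 1 fell, the transcription factor Olig1 (-0.86, SE 0.11; 1 and 3 blocked). Astrocyte markers had 0 of 12 past the threshold (1 and 8 blocked), erythroid markers 0 of 5 (2 and 0 adjusted over the list alone and blocked), endothelial and pericyte markers 0 rises and 1 fall of 12 (0 and 2 blocked), and fibroblast markers 0 rises and 1 fall of 15, Fbln1 (-0.49; 3 and 3 blocked). The sign of the median differed from the direction of the test for the hypoxia, GABAergic and endothelial lists. With library totals alone, rises and falls were 0 and 2 for ketone and fatty acid oxidation genes, 0 and 2 for heat shock genes and 1 and 0 for mitochondrial quality control.

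Over all genes, 862 rose, 658 fell and 13633 did not pass at 1 mM, and 153 and 112 of them changed at least 2-fold; with the replicate block, 2736 rose and 2770 fell. Without control replicate 1 the counts were 528 and 293, without control replicate 3 558 and 320, without 1 mM replicate 1 514 and 296, and without 1 mM replicate 3 509 and 338. With a minimum fold of 1.5, 129 rose and 37 fell, so that the share of rises was 77.7% in place of 56.7%.

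The comparison of 10 mM with control asks what the high dose changed. The stress genes that were higher at 1 mM were higher again: Hspa5 rose 7.10-fold, Ddit3 11.4-fold, Trib3 86.4-fold and Txnip 38.5-fold. Bdnf rose 2.22-fold. Of 78 ribosomal protein genes 47 rose, and falls were seen in 20 of 26 cholesterol synthesis genes, 15 of 18 microglial markers and 22 of 46 cell cycle genes, such as Ccne2. With an estimated correlation these lists lost their calls (adjusted p = 0.621, 0.103, 0.553 and 0.78).

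Bdnf stood at 8.23 ± 0.771 CPM at 10 mM (SD, n = 3), with 321 to 413 counts per library, against 3.70 ± 0.706 CPM in the control. Its log2 fold change was 1.15 (SE 0.14, adjusted p = 9.81e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Atf4 rose to 933 ± 67 CPM (1.76, SE 0.15, adjusted p = 8.18e-06), Ddit3 to 150.3 ± 3.60 CPM (3.51, SE 0.12, adjusted p = 9.85e-09) and Hspa5 to 2459 ± 178 CPM (2.83, SE 0.077, adjusted p = 3.61e-09). Txnip rose to 461 ± 37.1 CPM (5.27, SE 0.45, adjusted p = 7.46e-06), and without control replicate 2 its log2 fold change was 6.27 (adjusted p = 3.63e-09).

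All 40 genes of the ATF4 and CHOP list, Atf4 and Ddit3 included, rose at 10 mM over all genes tested. The same held adjusted over the list alone (median 2.76, camera adjusted p = 3.64e-157, 2.36e-24 with the replicate block, 0.0107 with an estimated correlation, 0.306 with both). Slc7a5 (3.50, SE 0.090), Asns (3.48, SE 0.090) and Slc7a3, a transporter of basic amino acids (5.19, SE 0.15), were among them, and Cass4 (5.69), Trim66 (5.34) and Nupr1 (5.01) had some of the largest rises of all genes. Of 40 ER chaperone and degradation genes, 37 rose and 0 fell, the same adjusted over the list alone (median 1.46, camera adjusted p = 7.92e-95, 1.43e-19 with the replicate block, 0.0182 with an estimated correlation, 0.306 with both). Examples were Creld2 at 2.76 (SE 0.062) and Hyou1 at 2.29 (SE 0.058). Of 20 aminoacyl-tRNA synthetases, 17 rose and 0 fell (the same adjusted over the list alone; median 1.31, camera adjusted p = 2.22e-38, adjusted p = 0.0812 with an estimated correlation). Examples were Nars at 2.15, Iars at 1.97 and Mars at 1.71. Microglial markers moved in the same libraries, with a median of -0.83.

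Of 42 genes of hexosamine, sugar nucleotide and N-glycan precursor synthesis, 25 rose and 4 fell at 10 mM (the same adjusted over the list alone; blocked 28 and 7; 19 and 6 with library totals alone, where the median was 0.137; median 0.23, camera adjusted p = 1.94e-05, adjusted p = 0.103 with an estimated correlation). Rpn1 (1.29, SE 0.052), the mannosyltransferase Alg2 (0.89, SE 0.051) and Gfpt1 (0.64, SE 0.039) rose. The members that fell, chosen after their values were seen, were Nagk, which salvages N-acetylglucosamine (-0.69), Alg8 (-0.69), Dpm2 (-0.31) and Gfpt2 (-0.46). Of 7 MondoA and ChREBP targets, 4 rose, Txnip, Arrdc4 (4.11, SE 0.11), Klf10 (2.26, SE 0.13) and Arrdc3 (0.92), and 1 fell, Dak (-0.45). An example was Arrdc3 and Dak chosen after their values were seen. The counts were 4 and 2 adjusted over the list alone, the median was 0.92 and the camera adjusted p = 1.94e-05. That call was lost with an estimated correlation (adjusted p = 0.0809) and with the replicate block (0.243).

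Of 26 cholesterol synthesis genes, 2 rose and 20 fell at 10 mM (the same adjusted over the list alone; median -0.48, camera adjusted p = 1.26e-09, adjusted p = 0.103 with an estimated correlation). Acat2 (-1.03, SE 0.047) and the sterol dehydrogenase Nsdhl (-1.39, SE 0.080) fell, and the members that rose, chosen after their values were seen, were Sc5d (0.20) and Ggps1 (0.34). Of 78 cytosolic ribosomal protein genes, 47 rose and 0 fell (48 adjusted over the list alone; median 0.29, camera adjusted p = 5.58e-05, adjusted p = 0.621 with an estimated correlation; 31 rose with library totals alone). Among them were Rpl12 (1.16, SE 0.077), Rpl10a (1.15, SE 0.067) and Rpl10 (0.98, SE 0.076). The gene Rpl12 contains Snora65 and Rpl10 contains Snora70, small nucleolar RNAs on the same strand that were tested as genes of their own. Of 28 ketone body and fatty acid oxidation genes, 4 rose and 14 fell (5 and 14 adjusted over the list alone; 6 and 21 blocked; median -0.33, camera adjusted p = 0.00608, adjusted p = 0.446 with an estimated correlation). Examples were Cpt2, which passes fatty acids into mitochondria, at -1.64 (SE 0.13) and Etfb, an electron carrier of the pathway, at -1.41 (SE 0.11). Of 58 nuclear genes of the respiratory chain, 4 rose and 24 fell (the same adjusted over the list alone; 11 and 30 blocked; median -0.085, camera adjusted p = 0.00627, adjusted p = 0.756 with an estimated correlation). Examples were Cox6b1 at -0.66 and Uqcrh at -0.71. Of 26 NRF2 targets, 4 rose, among them Slc7a11 (4.44) and Hmox1 (1.54), and 16 fell, among them Prdx1 (-0.83, SE 0.051), the same adjusted over the list alone.

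The NRF2 list had a median of -0.30, a mean of 0.023 and a camera adjusted p = 0.0492, directed downwards. That call was lost with an estimated correlation (adjusted p = 0.18) and without control replicate 2 (0.0517), control replicate 3 (0.0764), 1 mM replicate 1 (0.0598), 1 mM replicate 2 (0.0928), 1 mM replicate 3 (0.0841), 10 mM replicate 1 (0.0963), 10 mM replicate 2 (0.0785) or 10 mM replicate 3 (0.0538).

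Of 46 cell cycle genes, 0 rose and 22 fell at 10 mM (the same adjusted over the list alone; 4 and 32 blocked; median -0.33, camera adjusted p = 5.96e-04, adjusted p = 0.78 with an estimated correlation). Examples were Ccne2 at -2.07 (SE 0.17), Ccne1 at -1.82 (SE 0.17) and E2f1 at -1.43 (SE 0.16). Of 18 microglial markers, 0 rose and 15 fell (16 adjusted over the list alone; median -0.83, camera adjusted p = 7.86e-04, adjusted p = 0.553 with an estimated correlation). Examples were Cx3cr1 at -2.03 (SE 0.21) and Fcer1g, the signalling chain of antibody receptors, at -1.22 (SE 0.18). Tlr13 (-2.79), Plau (-2.70), Fcgr3 (-2.25) and Olig1 (-2.23) had some of the largest falls of all genes. Of 20 radial glia and progenitor markers, 0 rose and 8 fell (the same adjusted over the list alone; 2 and 16 blocked; median -0.23, camera adjusted p = 0.0148), with the fatty acid binding protein Fabp7 at -1.65 (SE 0.18) and Mfge8 at -0.80. The radial glia test was lost with an estimated correlation (adjusted p = 0.756) and without control replicate 3 (0.0521) or 10 mM replicate 2 (0.0551).

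**Figure D3:**
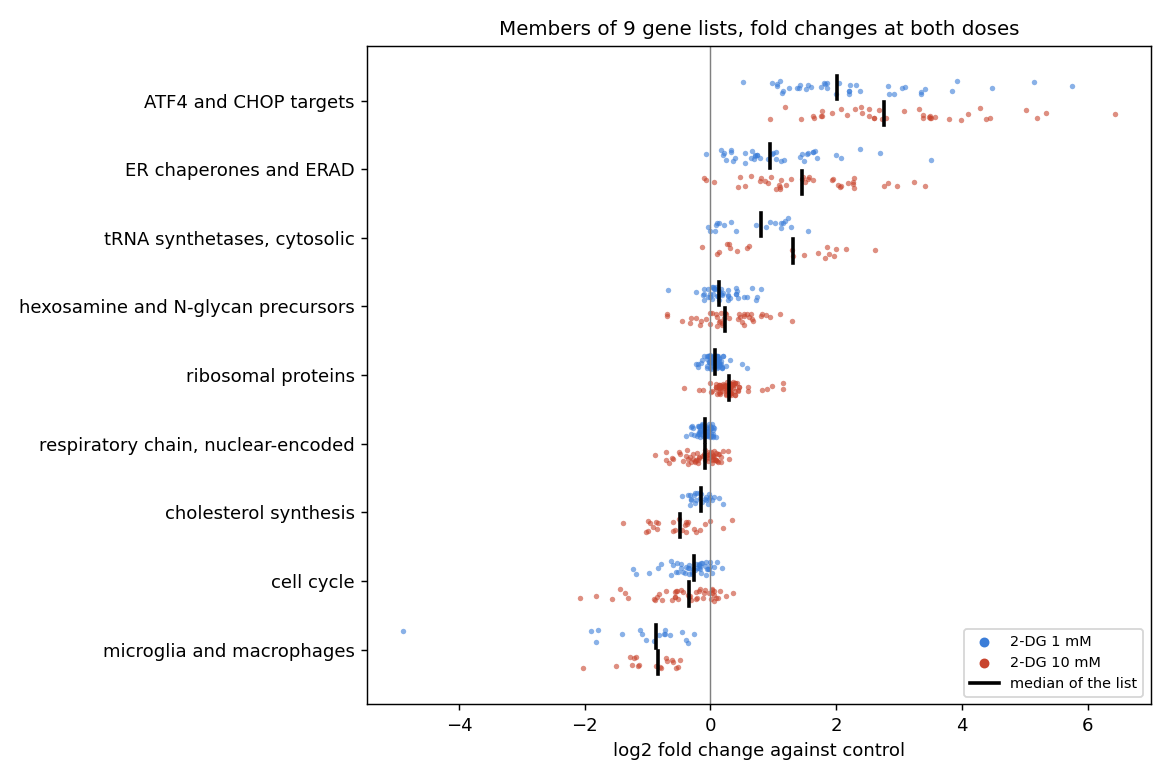
Log2 fold change against control (horizontal axis) of each member of 9 of the fixed gene lists at 1 mM and 10 mM, with 1 point per gene and a bar at the median. The ATF4 and CHOP targets had medians of 2.02 and 2.76 and the microglial markers had medians of -0.86 and -0.83.

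The other 17 lists did not pass camera at 10 mM (adjusted p from 0.124 to 0.973), with the counts adjusted over the list alone the same unless given. Of 16 neurotrophins and receptors, 2 rose, Bdnf and Ntrk3, and 5 fell (2 and 4 adjusted over the list alone; 2 and 10 blocked): Mt3 (-1.81, SE 0.20), Igf1 (-1.05, SE 0.14), Sort1 (-0.53, SE 0.050), the neurotrophin Ntf3 (-1.54) and the BDNF receptor Ntrk2 (-0.14), where Ntrk3, Ntf3 and Ntrk2 were chosen after their values were seen. Of 26 glycolysis genes, 5 rose and 10 fell, with Tpi1 at -0.79 (SE 0.057) and Pfkfb3 at 0.68 (SE 0.051). Of 21 hypoxia targets, 5 rose and 6 fell, with Vegfa at 2.87 (SE 0.094). Of 36 immediate early genes, 13 rose and 9 fell, with Jun at 1.25 (SE 0.084) and Nfil3 at 1.19 (SE 0.078). Of 42 autophagy and lysosome genes, 21 rose and 11 fell (24 and 12 adjusted over the list alone; 11 and 15 with library totals alone). Examples were Atg12 at 0.74 and Rragd at -0.82. Mitochondrial quality control had 6 rises and 3 falls of 19 (9 and 5 blocked), with Hspa9 at 1.36, and p53 targets had 7 and 5 of 25, with Gdf15 at 4.38 and Mdm2 at 0.69. Heat shock genes had 4 rises and 7 falls of 24 (8 and 9 blocked), AMPK and FOXO genes 6 and 5 of 21 (6 and 6 adjusted over the list alone; 9 and 8 blocked), and synapse genes 9 and 6 of 44 (9 and 4 adjusted over the list alone; 18 and 12 blocked). An example was Slc17a6, a vesicular glutamate transporter, at 0.52.

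Cell type lists at 10 mM had 2 rises and 7 falls of 25 markers of immature neurons (8 and 11 blocked), with Cd24a at -0.76 and Sox4 at 0.42, and 5 and 3 of 17 GABAergic markers (6 and 6 blocked). Examples were Gad1, which makes GABA, at 0.40 and Sst at -0.36. They had 0 rises and 3 falls of 11 oligodendrocyte markers (1 and 5 blocked), 1 and 2 of 12 astrocyte markers (1 and 9 blocked), 3 and 2 of 12 endothelial and pericyte markers (1 and 2 adjusted over the list alone; 3 and 4 blocked), 1 and 3 of 15 fibroblast markers (0 and 2 adjusted over the list alone; 5 and 5 blocked), and 1 and 0 of 5 erythroid markers (3 and 0 blocked). The median's sign differed from the direction of the test for the hypoxia and endothelial lists, and the mean's for the NRF2, heat shock, endothelial and p53 lists. With library totals alone, the medians of the immediate early, synapse, GABAergic and endothelial lists changed sign. Rises and falls by that scaling were 4 and 8 for synapse genes, 3 and 5 for GABAergic, 1 and 3 for endothelial, 0 and 6 for astrocyte and 1 and 11 for immature neuron markers. They were 6 and 9 for AMPK and FOXO genes, 6 and 6 for mitochondrial quality control, 4 and 6 for p53 targets, 2 and 30 for the respiratory chain (median -0.176), 4 and 2 for MondoA targets, 1 and 20 for cholesterol synthesis, 37 and 1 for ER genes and 16 and 1 for tRNA synthetases.

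Over all genes, 3899 rose, 3639 fell and 7615 did not pass at 10 mM, and 343 and 628 of them changed at least 2-fold. With the replicate block, 5213 rose and 5117 fell. With library totals alone the counts were 2850 and 4776, so that 37.4% of the calls were rises in place of 51.7%, and with a minimum fold of 1.5 they were 410 and 459.

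The comparison of 10 mM with 1 mM asks which genes depended on the dose. Of 40 ATF4 targets 35, and of 40 ER genes 33, were higher at the higher dose, with Hspa5 up 1.69-fold, Asns up 2.26-fold and Txnip up 3.20-fold, and Bdnf was up 1.47-fold. Cx3cr1 was 7.25-fold higher at 10 mM than at 1 mM. Of 26 cholesterol synthesis genes 18 were lower at the higher dose, with Nsdhl at -1.07. With an estimated correlation the cholesterol, ATF4 and ER lists lost their calls (adjusted p = 0.192, 0.192 and 0.194).

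Bdnf had a log2 fold change of 0.56 between the doses (SE 0.14, adjusted p = 0.0129 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1.87e-05 with the replicate block). The call was lost without 10 mM replicate 3 (0.49, adjusted p = 0.0533) and with a minimum fold of 1.5. Atf4 changed by 0.51 (SE 0.15, adjusted p = 0.0243), and its call was lost without 1 mM replicate 2 (0.34, 0.0706), 10 mM replicate 1 (0.51, 0.064) or 10 mM replicate 3 (0.46, 0.0795). Ddit3 changed by 0.59 (SE 0.10, adjusted p = 0.00214), Hspa5 by 0.76 (SE 0.072, adjusted p = 1.08e-04) and Txnip by 1.68 (SE 0.38, adjusted p = 0.00712). The largest rises among genes that met the rule were those of Cx3cr1 (2.86, SE 0.29), Klf10 (1.73, SE 0.13) and Arrdc4 (1.69, SE 0.097), and the largest falls were those of Krcc1 (-1.48, SE 0.15), Fhl4 (-1.43, SE 0.16) and Acad11, an enzyme of fatty acid oxidation (-1.38, SE 0.14).

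Between the doses, 35 of 40 ATF4 and CHOP targets rose and 0 fell (the same adjusted over the list alone; median 0.72, camera adjusted p = 6.6e-36, adjusted p = 0.192 with an estimated correlation). Examples were Asns at 1.18 (SE 0.082) and Slc7a5 at 1.11 (SE 0.082). Of 40 ER genes, 33 rose, such as Herpud1 (1.05, SE 0.092), and 1 fell, Dnajc10 (-0.24, chosen after its value was seen; 35 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 7.65e-24, adjusted p = 0.194 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases, 15 rose and 0 fell (16 adjusted over the list alone; median 0.40, camera adjusted p = 3.68e-17, adjusted p = 0.252 with an estimated correlation). Examples were Yars at 0.91 and Nars at 0.88. Of 26 cholesterol genes, 1 rose, Ggps1 (0.28, chosen after its value was seen), and 18 fell (1 and 20 adjusted over the list alone; median -0.35, camera adjusted p = 2.08e-12, adjusted p = 0.192 with an estimated correlation). An example was Acat2 at -0.72. Of 78 ribosomal protein genes, 34 rose and 0 fell (36 adjusted over the list alone; 59 blocked; 13 with library totals alone, where the median was 0.134; median 0.22, camera adjusted p = 2.71e-07, adjusted p = 0.487 with an estimated correlation). Examples were Rpl12 at 0.96 and Rpl10a at 0.85. Microglial markers had a median of 0.0395 between the doses (-0.0405 with library totals alone). Of 7 MondoA and ChREBP targets, 3 rose and 1 fell, Dak (-0.47, chosen after its value was seen; the same adjusted over the list alone; median 0.39, camera adjusted p = 0.00196, adjusted p = 0.194 with an estimated correlation, 0.481 with the block). Of 28 ketone and fatty acid oxidation genes, 1 rose and 7 fell (the same adjusted over the list alone; 5 and 13 blocked; median -0.21, camera adjusted p = 0.0128, adjusted p = 0.484 with an estimated correlation, and 0.116 without 10 mM replicate 2). Examples were Cpt2 at -1.27 and Etfb at -1.08. Of 42 hexosamine and N-glycan genes, 15 rose and 4 fell (18 and 4 adjusted over the list alone; 21 and 9 blocked; 11 and 7 with library totals alone, where the median was 0.06; median 0.14, camera adjusted p = 0.0348, adjusted p = 0.428 with an estimated correlation, 0.0666 with the block); Mgea5 rose (0.91, SE 0.072) and Ogt fell (-0.39, SE 0.039), each opposite to its change at 1 mM.

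The other 22 lists did not pass camera between the doses (adjusted p from 0.052 to 0.989), with the counts adjusted over the list alone the same unless given. Of 18 microglial markers, 1 rose, Cx3cr1, and 0 fell (4 and 2 blocked), and Cd68 had a value of 0.31 (adjusted p = 0.0841). Of 16 neurotrophins and receptors, 2 rose and 3 fell (2 and 7 blocked). An example was Mt3 at -0.95. Of 42 autophagy genes, 17 rose and 4 fell (8 and 4 with library totals alone; 22 and 8 blocked, list adjusted p = 0.029, and 0.43 with an estimated correlation too), and of 26 NRF2 targets, 3 rose, with Hmox1 at 0.72, and 7 fell (3 and 9 adjusted over the list alone; 4 and 14 blocked, list adjusted p = 0.029, and 0.43 with an estimated correlation too). Of 20 radial glia markers, 0 rose and 4 fell (3 adjusted over the list alone; 2 and 11 blocked, list adjusted p = 0.0316, and 0.43 with an estimated correlation too), with Fabp7 at -0.89, and of 46 cell cycle genes, 0 rose and 6 fell (5 adjusted over the list alone; 8 and 21 blocked). An example was E2f1 at -0.89. Of 58 respiratory chain genes, 5 rose and 13 fell (11 and 21 blocked), with Ndufb3 at -0.58, and of 26 glycolysis genes, 3 rose and 5 fell (6 and 10 blocked). Of 36 immediate early genes, 8 rose and 5 fell (10 and 5 adjusted over the list alone; 15 and 9 blocked). Examples were Jun at 0.81 and Jund at 0.55. Heat shock genes had 5 rises and 2 falls of 24 (11 and 3 blocked), mitochondrial quality control 5 and 2 of 19 (8 and 3 blocked), hypoxia targets 4 and 4 of 21 (7 and 6 blocked), p53 targets 4 and 4 of 25 (9 and 5 blocked) and AMPK and FOXO genes 7 and 3 of 21 (7 and 4 adjusted over the list alone; 9 and 6 blocked). Synapse genes had 5 rises and 2 falls of 44 (3 and 2 adjusted over the list alone; 16 and 14 blocked), markers of immature neurons 1 and 6 of 25 (7 and 10 blocked), and GABAergic markers 3 and 3 of 17 (6 and 6 blocked).

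Oligodendrocyte markers had 0 rises and 2 falls of 11 between the doses (0 and 4 blocked), with Olig1 at -1.37, astrocyte markers 0 and 1 of 12 (0 and 0 adjusted over the list alone; 2 and 5 blocked), fibroblast markers 0 and 1 of 15 (2 and 2 blocked), endothelial markers 0 and 0 of 12 (0 and 2 blocked), and erythroid markers 1 and 0 of 5 (1 and 1 blocked). The median's sign differed from the test's direction for the immediate early genes and the AMPK list, and the mean's sign for the immediate early, AMPK, GABAergic, endothelial and erythroid lists. With library totals alone, the medians of the hypoxia, heat shock, mitochondrial quality control, synapse, GABAergic and microglial lists changed sign. Rises and falls were then 4 and 6 for hypoxia targets, 3 and 2 for heat shock genes, 2 and 3 for mitochondrial quality control, 2 and 6 for synapse genes, 2 and 14 for NRF2 targets and 1 and 18 for the respiratory chain. For AMPK and FOXO genes they were 3 and 4, for GABAergic markers 2 and 3 and for endothelial markers 0 and 1.

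Between the doses, 2655 genes rose, 2076 fell and 10422 did not pass, and 62 and 223 of them changed at least 2-fold; with the replicate block, 4648 rose and 3880 fell. With library totals alone the counts were 1564 and 2961, so that 34.6% of the calls were rises in place of 56.1%, and with a minimum fold of 1.5 they were 38 and 33.

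Genes that changed at 1 mM mostly changed the same way at 10 mM. Of the 862 that rose at 1 mM, 812 also rose at 10 mM, and of the 658 that fell, 638 also fell. If calls at the doses were unrelated, 221.8 shared rises and 158 shared falls would be expected, as 49.7% of genes passed at 10 mM. In opposite directions, 1 gene passed. The shared genes were 95.4% of those called at 1 mM. Across genes, which are not independent replicates, the log2 fold changes at both doses had a Pearson correlation of 0.783, against 0.446 to 0.551 in 100 simulations with shared controls, and a covariance of 0.180 against a simulated mean of 0.0181. Of the genes that rose at 1 mM, such as Hspa5, 605 rose further at 10 mM, 26 turned back, such as Ogt, and 231 did not differ between the doses by the test. Of those that fell, 280, such as Ccne2, fell further, 7, among them Cx3cr1, turned back and 371 did not differ by the test.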

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

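The test of this part, which fits the entry beside the genes, was chosen after its counts were seen. The count table holds 1 entry that names no gene; its label reads enhancer, 3 kb and as, and its position, strand and meaning are not given in the sources used here. It drew attention because its counts lay above those of the controls: they summed to 115 over the 1 mM libraries and to 254 over the 10 mM libraries, against 33 over the control libraries. With all libraries of each group between 9 and 14, 22 and 49, and 66 and 104 counts, the groups did not overlap. When the entry was added to the genes tested with edgeR, its log2 fold change was 1.74 at 1 mM (SE 0.32, adjusted p = 0.00708), 2.91 at 10 mM (SE 0.30, adjusted p = 2.61e-05) and 1.18 between the doses (SE 0.25, adjusted p = 0.0057). No explanation of it was tested.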

How the results depend on the processing

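The replicate block with an estimated correlation was the only test here that was chosen after the data were seen. With the replicate block, 2736 genes rose and 2770 fell at 1 mM, 4648 rose and 3880 fell between the doses, and the share of 1 mM genes called at both doses was 88%. With a minimum fold of 1.5, 129 rose and 37 fell at 1 mM, 410 and 459 at 10 mM, and 38 and 33 between the doses, and Bdnf was no longer called at 1 mM (0.59) or between the doses (0.56), as this test asks for a larger change. With library totals alone 1564 genes rose between the doses. In the fit to 6 libraries Bdnf was not called at 1 mM (0.59, adjusted p = 0.0557). List tests past the threshold numbered 10, 13 and 8 in the main test for 1 mM, 10 mM and the doses. They numbered 14, 12 and 9 with the replicate block and 5, 2 and 0 with an estimated correlation. With fry, which does not test a list against other genes, they numbered 6, 17 and 11. By camera with the block and an estimated correlation together they numbered 0, 0 and 0. With at least 50 counts in 3 libraries, the correlation between doses was 0.831 and the share 96.7%. Over the fits that each left out 1 library, rises at 1 mM numbered 509 to 894 and falls 293 to 674, Bdnf lay at 0.51 to 0.76 at 1 mM and 0.49 to 0.63 between the doses, the correlation at 0.743 to 0.79 and the share at 94.3% to 97.6%. The cause of these differences was not tested apart from the minimum fold. Of 4254 further values of named genes, 4128 kept their side of the threshold, 72 lost a call and 54 gained one. Where the main or the further value passed, 0 changed direction. Direction was not compared where neither passed.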

Other observations

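The tests chosen after the result was seen were both Cochran Q tests, the test on intergenic long non-coding RNAs, the permutation test against ribosomal protein genes and the list of decay factors. Of 471 long non-coding RNAs tested, 43 rose and 155 fell at 10 mM, with a median log2 fold change of -0.37, whereas 21 rose and 7 fell at 1 mM. Of 20 entries for transcripts that host small nucleolar RNAs, 11 rose and 2 fell at 10 mM with a median of 0.79, and 7 rose and 0 fell at 1 mM with a median of 0.23 by edgeR. Snhg12 rose by 1.13 at 1 mM and 2.61 at 10 mM, Snhg1 by 0.84 and 2.35, and Gas5 by 0.33 and 1.00, while Snhg18 (-0.56, adjusted p = 0.0351) and D7Ertd715e (-0.43) fell at 10 mM. The entries D7Ertd715e and C230091D08Rik both belong to Snhg14, so that 1 gene is counted 2 times among the 20. These genes were chosen after their values were seen.

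Of 18 microglial genes, 11 fell at 1 mM and 15 at 10 mM, and the list lost its call with an estimated correlation (adjusted p = 0.176 and 0.553). A loss or lower share of microglia is a candidate explanation. One common amount for all 18 members was argued against at 1 mM (chi-square p of Cochran's Q = 2.27e-50, 6.67e-07 without Cx3cr1). Between the doses the same test rested largely on Cx3cr1 (2.52e-17, 0.0452 without Cx3cr1). Cochran's Q takes the SEs as known and the members as independent, so 0.0452 cannot decide on a common change between the doses. For the trend of low-count genes, random lists matched on expression had a typical median of -0.0299 at 1 mM and -0.207 at 10 mM. The microglial medians of -0.86 and -0.832 lay at percentile 0 of 10000 such lists at each dose. Those lists treat genes as independent, whereas the estimated correlation among the members was 0.46 and 0.44. The percentiles therefore cannot decide whether the difference exceeds the spread of such a list. Abundant members in the control included Tyrobp (10.6 CPM) and Csf1r (10.3 CPM), at 5.01 and 6.22 CPM at 1 mM; 1 of the 18 members also stands in another list, no sort or gate is given in the sources used here, and how many members neurons express was not tested. A partial loss together with changes within microglia may remain, and the biological difference of the design, the 2-DG dose, stays open.

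For the long non-coding RNAs at 10 mM, the median lay at percentile 0 among protein-coding sets matched on expression. Of the medians of those sets, 95% lay between -0.267 and -0.139. The sets were drawn as if genes were independent, so the percentile cannot decide on the trend of low-count genes. GC content, length and expression may account for part of the fall, as the median after regression on them was -0.15 (95% bootstrap interval -0.19 to -0.066) in place of -0.37 (-0.43 to -0.30). For reads from overlapping coding genes, intergenic long non-coding RNAs had a median of -0.31 (-0.41 to -0.24). The rule asked only for an interval below 0, where the matched protein-coding sets also lay. It therefore could not decide on overlapping reads. A biological effect of the dose stays open, as a hypothesis found and tested on the same data.

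For the host transcripts at 10 mM, ribosomal protein genes had a smaller median rise, 0.29 against 0.79. The permutation p was 1e-05, the smallest that 100000 permutations can give. That test exchanged genes as if they were independent and was chosen after the rise was seen. It therefore cannot decide whether a general rise of ribosomal protein genes was involved. Less nonsense-mediated decay could not be told apart from other explanations: 7 other targets had a median at percentile 86 of matched lists, with members going both ways (Upp1 -1.94, Tbl2 0.71), and 7 decay factors at percentile 95.2. Both lay below the upper bound on the percentile, which was written before the result was seen for the targets and after it for the factors. The rule that leaves them undecided, because the bound lies within their spread, was added after the values were seen. Less decay may therefore contribute, and the 2-DG dose stays open as a biological difference.

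For the counts of genes past the threshold, 10 splits of 6 libraries are too few for a share under 0.05. By edgeR the real split gave 1520, 7538 and 4731 genes for 1 mM, 10 mM and the doses, with 1 of 10 splits as large in each, and the highest other gave 0. Among the 4 splits that part 3 pairs of replicate numbers, the real one included, the others gave 0, and so did the 6 that part 1 pair. Every split but the real one mixed libraries of both groups, which puts the difference between the groups into the spread. Counts of 0 were therefore likely beforehand and are no evidence of their own.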
